A study of Mus musculus with 2 samples.

How the data were processed

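Chromatin immunoprecipitation with sequencing for H3K9ac, a histone H3 acetylation found at active promoters, was carried out on the facial prominences of mouse embryos at embryonic day 15.5. There was 1 group of 2 biological replicates. Per the labels, replicate 1 was pooled from 78 embryos and replicate 2 from 62 embryos of mixed sex and of the B6NCrl strain, and libraries were selected for fragments of 300 to 500 bp. The design holds no second condition, so the comparisons are between the replicates and, within the samples, between genes and regions.

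The deposited files were 4 peak lists in the narrowPeak layout on mouse build mm10. Per the deposited file descriptions, 1 list was called from each replicate against 1 control file and another from the pooled reads of both replicates with 2 control files, and the replicated list was made from these lists. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. For each peak the authors deposited a fold enrichment, the ratio of the immunoprecipitated signal to the control as the peak caller wrote it. The authors also deposited −log10 p and −log10 q for each peak, a display score that was not used in any result, and the offset of the summit from the peak start. The lowest −log10 p was 2.03 in replicate 1 and 2.01 in replicate 2. Lists called at such a level hold many weak peaks, and each list depends on its own depth. Reads were not analysed here and the depth of each library is unknown, so intervals below cover the counting of peaks or genes, not reads. A fold enrichment is the authors' value for that peak and was used to describe and rank peaks within a list. Values of both replicates are printed side by side, and their mean was used for ranking within gene lists.

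Peak positions were checked against the lengths of the GRCm38.p6 chromosomes, which carry the same sequence as mm10, and 0 peaks ran past a chromosome end. Protein-coding genes and their transcription start sites (TSSs) came from the GENCODE M21 basic annotation, in which 21728 genes with distinct symbols lay on chromosomes 1 to 19 and X, with 41220 TSSs. Peaks on chromosome Y, the mitochondrial genome and unplaced scaffolds were left out of the comparisons. A gene was called marked in a replicate when a peak of that replicate overlapped the interval within 1 kb of any of its TSSs, and marked when this held in both replicates. An unmarked gene may still carry the mark in few cells of the tissue. How well reads map to gene copies of like sequence was not examined. A peak was assigned, in this order, to a protein-coding promoter, another annotated TSS, an exon, an intron or intergenic sequence, and exonic, intronic and intergenic peaks were called distal. Peaks of the replicates were counted as shared when at least 50% of either peak was covered by the other. Chance levels came from 100 shuffles of the peaks within their chromosomes, outside assembly gaps.

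Gene lists for cell types, signalling pathways and gene families, 33 in all, were fixed before the data were examined. Marked members of a list were compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 33 lists and calls at an adjusted p below 0.05. Odds ratios given with Fisher's test had 0.5 added to each cell. The height of a list was the median fold enrichment of its marked members at the tallest promoter peak, placed among 10000 random lists of marked genes of the same size, for the 24 lists with at least 3 marked members. The mean number of distal replicated peaks in a gene and 50 kb on either side was placed among 10000 random lists matched on 10 classes of the searched length. A percentile describes these samples and is not a test between conditions. Genes are not independent replicates and neighbours can share a peak, so each p describes these 2 samples. A neighbour in the text is the TSS of another protein-coding gene within 2 kb. The CpG ratio of a promoter is the observed over expected CpG count within 500 bp of the 5′-most TSS of the gene. A gene marked at another of its TSSs was thus classed by a promoter that may lack the peak. A stratified exact test over 10 equal classes of this ratio, the CpG classes, was run beside each Fisher's test. Its odds ratio is a Mantel-Haenszel ratio over the classes, with 0.05 added to each cell. For lists with none or all of their members marked, the size of either odds ratio depends on the added value. Intervals of shares are 95% Wilson intervals.

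Named genes were fixed by rule: of each list, the 2 marked members with the highest mean fold enrichment and the unmarked members, all of them up to 5 and otherwise the first 3 in list order; the 10 genes with the widest and the 10 with the highest promoter peak of the replicated list; the 5 highest promoters with a peak in 1 replicate only, for each replicate; the 5 genes with most distal peaks within 50 kb; the 5 highest distal peaks; and every Hox gene. Genes named outside this rule are said to be so. Alternatives covered promoter windows of 500 and 2500 bp, other overlap rules, a stricter −log10 q of 5, the authors' replicated list, 1 TSS per gene, strata of CpG ratio, genes without neighbours, search distances of 20 and 100 kb, and leaving out each replicate. The TSSs of every annotated transcript, and the strata of CpG ratio for the X chromosome, were chosen after seeing the data.

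The methods were tested on simulated data. Of 200 simulated null lists of 20 genes among the 21728 genes, 3% had a Fisher's p under 0.05, and of 100 lists simulated as highly marked 99% did. Of 40 lists of 20 genes with unchanged heights, 7.5% fell outside the central 95% of random lists. Overlaps were compared with bedtools 2.31.1. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and samtools 1.23.1 read the genome.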

Results

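H3K9ac was mapped in the facial prominences of mouse embryos at embryonic day 15.5, the tissue that forms the upper and lower jaws, palate, nose and skin of the face. The 2 biological replicates form 1 group. Replicate 1 held 44266 peaks over 21.7 Mb and replicate 2 held 38881 peaks over 20.0 Mb. Median peak width was 284 bp in replicate 1 and 311 bp in replicate 2, and median fold enrichment, the authors' ratio over control, was 3.20 and 3.52. The pooled reads gave 45000 peaks, and the authors' replicated list held 21624 peaks with a median width of 777 bp and a median fold enrichment of 5.30. Read depth is unknown.

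The first comparison asked how far the replicates share their peaks. On chromosomes 1 to 19 and X, 20987 of 44241 peaks of replicate 1 (47.4%, 95% interval 47.0 to 47.9) overlapped a peak of replicate 2, and 21544 of 38863 peaks of replicate 2 (55.4%, 54.9 to 55.9) overlapped one of replicate 1. The mean of these 2 shares was 51.4% (SD 5.66), against 1.15% for shuffled peaks of replicate 1. Both shares come from 1 comparison of the replicates, so the SD is not a spread between independent measurements. The shared part depended on the significance of the peak. Below a −log10 q of 2, 13.0% and 16.1% of the peaks of replicates 1 and 2 were shared. Between 5 and 10 the shares were 93.2% and 89.0%, and at 20 or more all 4490 and 4841 peaks were shared. Fold enrichment ranked alike in the replicates, with a Spearman correlation of 0.802 across 15782 peak pairs that matched one to one. This correlation is across peaks, which are not independent replicates. With only peaks of −log10 q of at least 5 in both lists, the mean of the 2 shares was 86.5% (SD 3.57, again from 1 comparison).

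**Figure D1:**
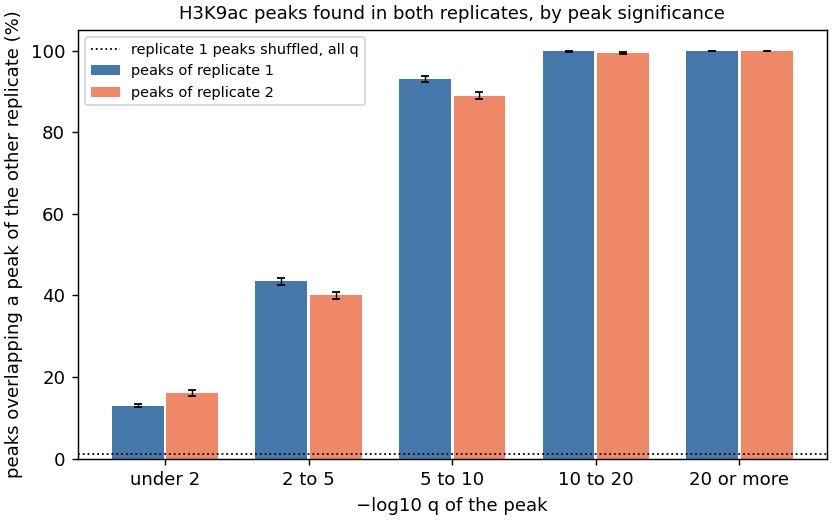
Share of H3K9ac peaks (%) that overlap a peak of the other replicate, by −log10 q of the peak, for replicate 1 and replicate 2; bars are shares, whiskers are 95% Wilson intervals and the dotted line is the mean of 100 shuffles of replicate 1 peaks. The share goes from 13.0% and 16.1% below a −log10 q of 2 to 100% at 20 or more.

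The second comparison asked where the mark lies. Of the 21612 replicated peaks on chromosomes 1 to 19 and X, 16327 (75.5%, 95% interval 74.97 to 76.1) lay at protein-coding promoters, against 3.22% of shuffled peaks. A further 8.15% lay at other annotated TSSs, 3.29% in exons, 6.61% in introns and 6.404% between genes. Promoter peaks were the tallest and widest class, with a median fold enrichment of 6.42 and a median width of 922 bp, while the 3524 distal peaks had a median fold enrichment of 3.35 and a median width of 436 bp. In the longer lists of the single replicates the promoter share was lower, 45.3% in replicate 1 and 53.3% in replicate 2, and introns held 23.6% and 19.5% of peaks.

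**Figure D2:**
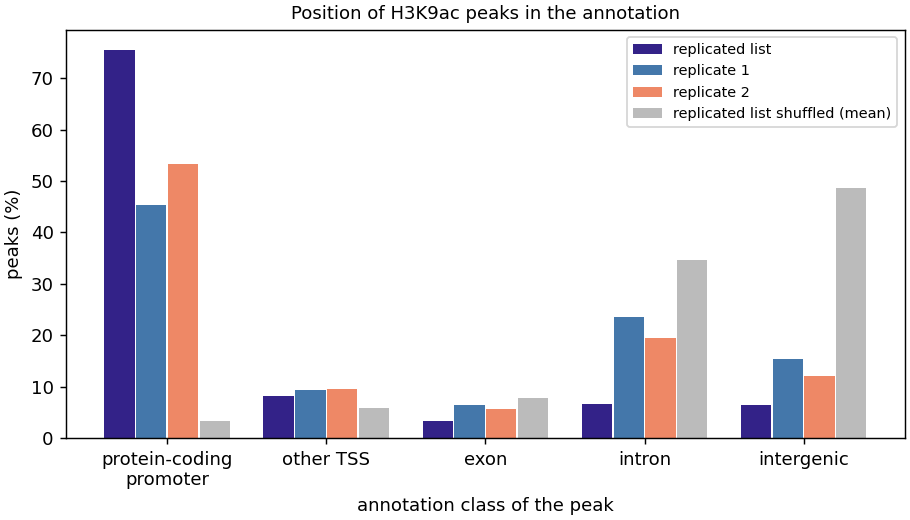
Share of peaks (%) in each annotation class for the replicated list, replicate 1, replicate 2 and the mean of 100 shuffles of the replicated list. Protein-coding promoters hold 75.5% of replicated peaks, 45.3% and 53.3% of the peaks of replicates 1 and 2, and 3.22% of shuffled peaks.

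The third comparison asked which promoters carry the mark. In both replicates, 12728 of 21728 protein-coding genes (58.6%, 95% interval 57.9 to 59.2) were marked, 61.3% in replicate 1 and 60.7% in replicate 2. A peak was found in replicate 1 only for 586 genes and in replicate 2 only for 469 genes, and 7945 genes had a peak in neither. Marking followed the CpG content of the promoter, from 2.16% of genes in the lowest of 10 classes of CpG ratio to 96.9% in the highest. With only peaks of −log10 q of at least 5, 49.0% of genes were marked.

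The tallest promoter peaks are given in order of fold enrichment. Srsf4, which encodes a splicing factor, led the replicated list with a fold enrichment of 21.9 at chr4:131873622-131875163 (mm10), with 18.7 in replicate 1 and 19.5 in replicate 2. Atf4, a transcription factor of the stress response, followed with 21.4 at chr15:80255218-80257257, with 15.2 and 22.96 in the replicates. Atp5g3, a subunit of the mitochondrial ATP synthase, had 20.8 and Srsf6, a second splicing factor, 19.7. The polyubiquitin gene Ubc, whose peak overlaps the predicted gene Gm10382, also had 19.7. The other peaks of this group lay at Mat2a, the enzyme that makes S-adenosylmethionine, at Surf4 and its neighbour Stkld1, at the histone methyltransferase gene Kmt5b, at the transcription factor gene Sp3 and at Msl1, a subunit of a histone acetyltransferase complex, with fold enrichments of 19.4, 19.1, 18.8, 18.7 and 18.6.

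Other genes led by width in the replicated list, whose peaks have the coordinates of pooled peaks. Its widest promoter peak, 9525 bp at chr14:28504046-28513570, covered the promoter and the 5′ part of Wnt5a, a secreted WNT ligand of face and limb outgrowth. Its tallest peak had a fold enrichment of 9.45 in replicate 1 and 10.7 in replicate 2 and was 3513 and 3421 bp wide there, with further separate peaks over the rest of the region. Fgfr2, a receptor for fibroblast growth factors, had a peak of 6646 bp, and Tbx2, a T-box transcription factor, one of 6541 bp. Peaks of 6536 bp at Tnrc18, 6307 bp at Bcl11a, 5919 bp at Mn1 and 5799 bp at Alx4, a homeobox gene of the frontonasal mesenchyme, came next. The group ended with Marcks at 5440 bp, Arhgef17 at 5251 bp and Nrp2, a receptor for semaphorins, at 5232 bp. The order depends on the list: in the single replicates Tnrc18 had the widest peak of all, with 5240 and 5378 bp. The tallest promoter peaks of the other 8 genes were narrower there than the listed widths. They had 4364 and 1138 bp at Mn1, 2098 and 3065 bp at Marcks and 1130 and 532 bp at Nrp2. At Fgfr2 they had 4052 and 1701 bp, but the listed peak, at chr7:130259954-130266599, was not the tallest Fgfr2 promoter peak of the replicated list. The tallest, with a fold enrichment of 12.3, lay at chr7:133121525-133125190, at the 5′ end of the annotated span of Fgfr2, chr7:130162451-133123350. Fgfr2 has a neighbour, and this peak, far from the listed one, may belong to another gene. The replicate widths at Fgfr2 may thus belong to another peak than the listed one.

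The fourth comparison asked which gene lists were marked more or less often than other genes. Of 33 lists, 9 were called higher and 13 lower, and within CpG classes 2 and 9. Of the 24 lists with at least 3 marked members, 3 had heights above the central 95% of random lists and 13 below. The 3 were the ribosomal, proteasome and hedgehog lists. Low medians were found for neurons (3.32), Hox genes (3.34), brain factors (3.65), olfactory epithelium (3.83), chondrocytes (3.85), skeletal muscle (3.86), surface epithelium (4.11), WNT ligands (4.16), endothelium (4.20), FGF ligands (4.65), retinoic acid genes (4.95), WNT feedback genes (5.39) and facial transcription factors (5.85). Without replicate 1 the WNT feedback and retinoic acid lists stood inside, at percentiles 9.45 and 8.385, and the osteoblast and complex I lists outside, at 0.84 and 99.65. Without replicate 2 the endothelium and retinoic acid lists stood inside, at 3.205 and 2.59. The random lists for height were not matched on CpG ratio. The median fold enrichment of marked genes was 6.01 in the lowest of the 10 CpG classes, 4.66 in class 4 and 8.95 in the highest. The height percentiles thus do not separate the lists from the CpG content of their promoters. Transcription factors of the cranial neural crest and facial mesenchyme were marked in 41 of 43 cases (95.3%), with the same number in each replicate alone. The odds ratio was 11.8 and the adjusted p of Fisher's exact test 2.96e-07. Prrx1, a homeobox gene of craniofacial mesenchyme, had a fold enrichment of 11.6 in replicate 1 and 11.7 in replicate 2, and Twist1, a bHLH factor of the neural crest, had 11.7 and 10.7. Hand1, which is expressed in the distal part of the mandibular arch, and Tbx22, a palate gene on the X chromosome, had no promoter peak in either replicate. The list was not tall: its median of 5.85 stood at percentile 0.86 of random lists. The call held within CpG classes, with an odds ratio of 9.32 and an adjusted exact p of 0.0148. With a window of 500 bp 38 were marked and the odds ratio was 5.16, and with a −log10 q of at least 5 it was 3.33 with 33 marked.

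Feedback genes of the FGF and WNT pathways and genes of the BMP and TGF-beta pathways were marked nearly throughout. All 17 FGF pathway feedback genes were marked (odds ratio 24.8, adjusted p of Fisher's exact test 0.000396), with fold enrichments of 11.5 and 13.0 at the receptor gene Fgfr1 and of 11.5 and 11.98 at the inhibitor gene Spred1. All 25 WNT pathway feedback and target genes were marked (odds ratio 36.1, adjusted p of Fisher's exact test 7.08e-06), with 11.1 and 12.5 at Axin1, a scaffold of the β-catenin destruction complex, and 11.8 and 11.2 at Lgr4, an R-spondin receptor. Of BMP and TGF-beta pathway genes, 21 of 22 were marked (odds ratio 10.2, adjusted p of Fisher's exact test 0.00047), with 10.2 and 13.7 at Smad6 and 13.1 and 9.12 at Smad7, both inhibitory SMADs. The exception was Bmp5, a BMP ligand with a peak in replicate 1 only, so that without replicate 2 all 22 were marked and the odds ratio was 28.5. Genes of mouse cleft lip and palate were marked in 34 of 39 cases (odds ratio 4.44, adjusted p of Fisher's exact test 0.000307). Lrp6, a WNT co-receptor, had 11.2 and 15.2, and Ryk, a WNT receptor, 12.4 and 13.5. The 5 unmarked members were Tbx22, the GABA-synthesis gene Gad1, the ligand genes Wnt9b and Fgf8, each with a peak in 1 replicate, and the forkhead gene Foxe1. Within CpG classes these 4 calls ended, with odds ratios of 7.10, 11.8, 5.92 and 1.33 and adjusted exact p of 0.243 for the FGF, 0.0849 for the WNT, 0.233 for the BMP and TGF-beta and 0.644 for the cleft list. The FGF and WNT lists were marked in full, so no higher share was possible there. For them the end of the call does not show that CpG content accounts for the marking. At a −log10 q of at least 5 the WNT and the cleft list were no longer called, with adjusted p of Fisher's exact test of 0.0899 and 0.0937, and the FGF and the BMP and TGF-beta odds ratios were 6.47 and 4.29; with 1 TSS per gene the cleft odds ratio was 2.46.

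Hedgehog pathway genes had tall promoter peaks. Of these, 11 of 14 were marked, which missed the threshold (odds ratio 2.32, adjusted p of Fisher's exact test 0.232), and the median fold enrichment of 9.64 stood at percentile 98.5. Boc, a hedgehog co-receptor, had 12.6 in replicate 1 and 13.98 in replicate 2, and Smo, the signal transducer, 11.4 and 13.97. The 3 unmarked genes were the ligand genes Shh, without a peak in either replicate, and Ihh and Dhh, with a peak in replicate 1 only at 2.99 each. Without replicate 2, 13 of 14 were marked, the odds ratio was 5.69 with an adjusted p of Fisher's exact test of 0.0218, and the height stood at percentile 87.0. Within CpG classes the direction turned, with an odds ratio of 0.474.

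Markers of surface and oral epithelium were marked in 18 of 22 cases (odds ratio 2.91, adjusted p of Fisher's exact test 0.0445), at a median fold enrichment of 4.11, below all 10000 random lists. Klf5, an epithelial transcription factor, had 8.07 and 8.48, and Pitx2, a homeobox gene of oral ectoderm, 5.53 and 6.24. Of the 4 unmarked members, Trp63, the regulator of stratified epithelium, and Sfn had a peak in replicate 2 only, the basal keratin gene Krt5 had one in replicate 1 only, at 3.23, and Krt15, a further keratin gene, had none. The call ended with a window of 500 bp, where 14 were marked (adjusted p of Fisher's exact test 0.712), and with 7 marked at a −log10 q of at least 5 the direction turned. It also ended with 1 TSS per gene, with every annotated transcript and within CpG classes, with adjusted p of Fisher's or the stratified exact test of 0.0826, 0.0717 and 0.0849, although the odds ratio within CpG classes was 4.45. The odds ratio was 5.31 without replicate 1 and 5.49 with a window of 2500 bp. Genes of terminal epidermal differentiation were marked in 1 of 18 cases (odds ratio 0.0605, adjusted p of Fisher's exact test 1.12e-05): Krt10, a keratin of suprabasal cells, had 7.83 and 6.91, while Krt1, Krt2 and the loricrin gene Lor had no peak. The Krt10 peak, at chr11:99385909-99386942, lay inside the gene at the downstream one of its 2 annotated TSSs, and with 1 TSS per gene 0 of 18 were marked (odds ratio 0.0207), while with a window of 2500 bp or every annotated transcript 2 were (0.101 and 0.102). Of the 8 enamel and dentin matrix genes, among them Amelx, Ambn and Enam, 0 were marked (odds ratio 0.0416, adjusted p of Fisher's exact test 0.0015), and of 67 hair keratins and keratin-associated proteins, among them Krt31, Krt32 and Krt34, also 0 (odds ratio 0.0052, adjusted p of Fisher's exact test 2.15e-25). The epidermal and enamel calls ended within CpG classes, with odds ratios of 0.474 and 0.177 and adjusted exact p of 0.715 and 0.644, and the hair keratin odds ratio there was 0.0189. With 0 of 8 enamel genes marked no lower share was possible. The end of the enamel call thus does not trace the result to CpG content.

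**Figure D3:**
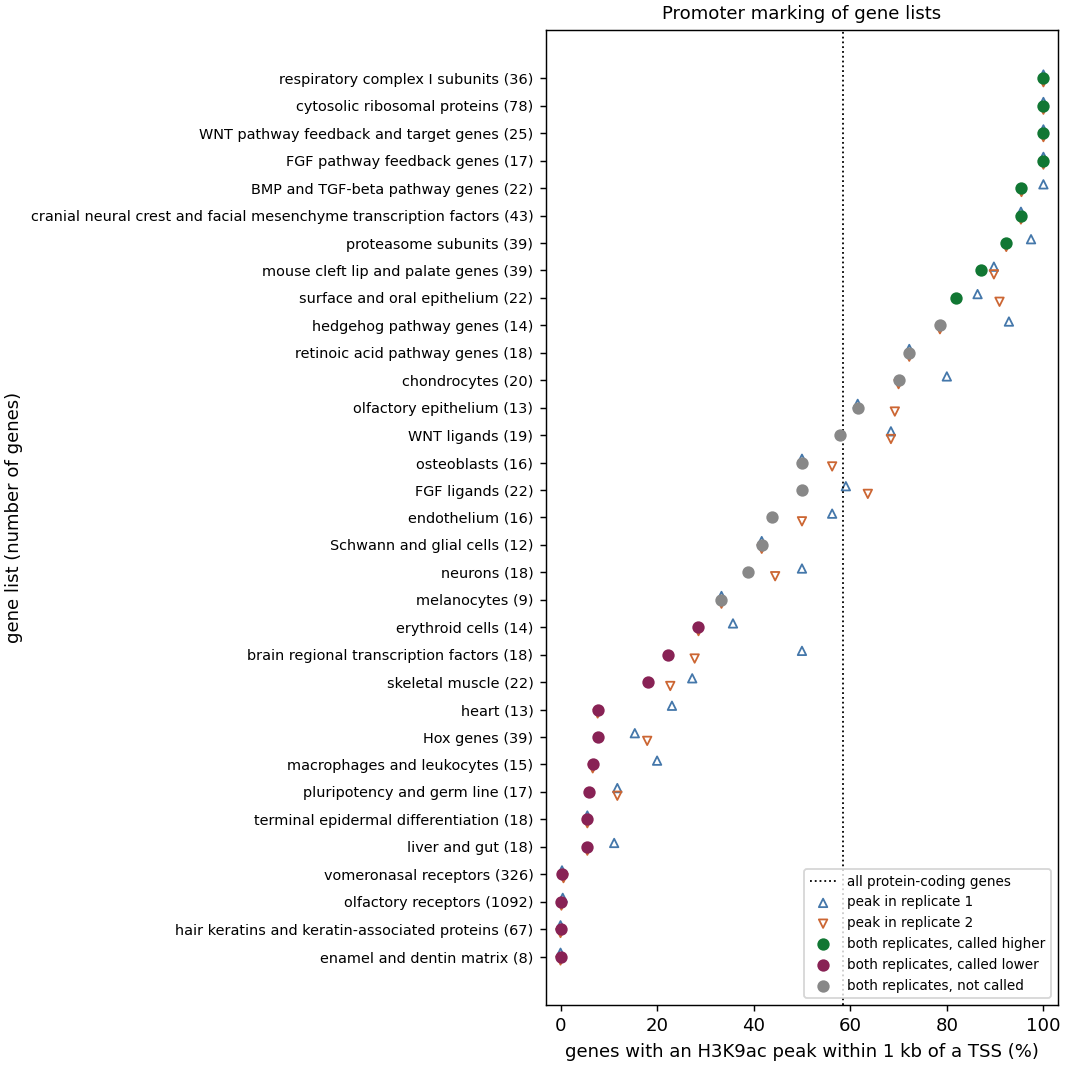
Share of genes (%) with an H3K9ac peak within 1 kb of a TSS for 33 gene lists, with the number of genes in brackets; filled points stand for a peak in both replicates, coloured by the call, open triangles for each replicate alone, and the dotted line for all protein-coding genes (58.6%). Ribosomal, complex I, WNT feedback and FGF feedback genes stand at 100%, and olfactory receptors, hair keratins and enamel genes at 0%.

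Lists of skeletal and neural cell types missed the threshold of Fisher's exact test. Chondrocyte genes were marked in 14 of 20 cases (odds ratio 1.58, adjusted p of Fisher's exact test 0.418). Pth1r, the parathyroid hormone receptor, had 7.57 and 6.74 and Sox9, the regulator of cartilage, 5.99 and 6.57, while Col9a1 and Matn1 of the cartilage matrix had no peak and Cnmd had one in replicate 1 only. At a −log10 q of at least 5, 3 of 20 chondrocyte genes were marked and the list was called lower (odds ratio 0.208, adjusted p of Fisher's exact test 0.00489), and within CpG classes the odds ratio was 3.07 (adjusted exact p of 0.0929). Osteoblast genes were marked in 8 of 16 cases (odds ratio 0.707, adjusted p of Fisher's exact test 0.653), with 7.10 and 10.5 at Sparc, a bone matrix protein, and 8.98 and 4.20 at the collagen gene Col1a1. The osteocalcin genes Bglap and Bglap2 and the sialoprotein gene Ibsp had no peak. The direction of the osteoblast list turned within CpG classes, with an odds ratio of 3.74 and an adjusted exact p of 0.0586. Neuronal genes were marked in 7 of 18 cases (odds ratio 0.461, adjusted p of Fisher's exact test 0.141), led by Map2 with 5.53 and 5.74 and Gap43 with 3.92 and 3.74, and Stmn2, Elavl3 and Snap25 were unmarked. The neuronal list was called lower at a −log10 q of at least 5 (adjusted p of Fisher's exact test 0.000357) and within CpG classes (adjusted exact p of 0.00119). Olfactory epithelium genes were marked in 8 of 13 cases (odds ratio 1.09, adjusted p of Fisher's exact test 1), with 6.05 and 4.66 at Emx2 and 4.59 and 5.49 at the adenylyl cyclase gene Adcy3. Omp, Cnga2, Neurod1 and Foxg1 had no peak, and Neurog1 had one in replicate 2 only. This list too was called lower at a −log10 q of at least 5 (adjusted p of Fisher's exact test 0.0327). The direction also turned within CpG classes, with an odds ratio of 0.377 (adjusted exact p of 0.17), with 1 TSS per gene, with 0.884, and without replicate 2, with 0.977.

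Glial, pigment and endothelial lists also missed the threshold. Schwann and glial genes were marked in 5 of 12 cases (odds ratio 0.518, adjusted p of Fisher's exact test 0.322). The myelin gene Mpz, which has a neighbour, had 11.8 and 7.94 and the myelin gene Mbp 4.61 and 5.48, and Sox10, Plp1 and Foxd3 were unmarked. Melanocyte genes were marked in 3 of 9 cases (odds ratio 0.381, adjusted p of Fisher's exact test 0.232), with 5.67 and 7.24 at Mitf, the regulator of pigment cells, and 4.61 and 3.62 at Kit, and none at the pigment enzymes Tyr, Tyrp1 and Dct. The melanocyte list turned in direction within CpG classes, with an odds ratio of 1.33 (adjusted exact p of 1), and had 0.245 with a window of 500 bp and 0.184 at a −log10 q of at least 5. Endothelial genes were marked in 7 of 16 cases (odds ratio 0.558, adjusted p of Fisher's exact test 0.379), with 8.99 and 7.74 at Fli1 and 4.83 and 4.49 at Sox18. Pecam1 had a peak in replicate 1 only, at 3.23, and Cdh5 and Tek had none. At a −log10 q of at least 5 the endothelial list was called lower (odds ratio 0.27, adjusted p of Fisher's exact test 0.0325), and with a window of 2500 bp its odds ratio was 0.847.

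Muscle and blood genes were marked less often. Skeletal muscle genes were marked in 4 of 22 cases, 6 in replicate 1 and 5 in replicate 2 alone (odds ratio 0.172, adjusted p of Fisher's exact test 0.000307). Mylpf, a myosin light chain gene with a neighbour, had 11.3 and 11.0, and Pax7, the gene of muscle progenitors, 3.46 and 4.99. The replicated peak at Mylpf lay wholly upstream of the gene and may belong to the neighbour. The myogenic regulators Myf6 and Myog had no peak and Myod1 had one in replicate 2 only, at 2.86. Erythroid genes were marked in 4 of 14 cases (odds ratio 0.303, adjusted p of Fisher's exact test 0.0445), with 6.69 and 7.49 at the transferrin receptor gene Tfrc and 5.10 and 6.91 at Klf1, and none at the globin genes Hba-a1, Hba-a2 and Hbb-bt. Of 15 macrophage and leukocyte genes, 1 was marked, Coro1a with 3.00 and 4.29 (odds ratio 0.073, adjusted p of Fisher's exact test 0.000102), and Ptprc, Csf1r and Spi1 were not. The erythroid call ended without replicate 2 (odds ratio 0.366), with 1 TSS per gene (0.328) and without genes with a neighbour (0.362), with adjusted p of Fisher's exact test of 0.0866, 0.0826 and 0.0946, and its odds ratio was 0.147 with a window of 500 bp. The leukocyte odds ratio was 0.177 without replicate 2, with 3 genes marked, 0.128 in the replicated list and 0.0336 at a −log10 q of at least 5, where that of muscle was 0.0726. Within CpG classes the 3 calls ended, with odds ratios of 0.416, 1.32 and 0.256 and adjusted exact p of 0.204 for muscle, 0.693 for erythroid genes, where the direction turned, and 0.539 for leukocytes.

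Genes of other organs were also marked less often. Of 18 liver and gut genes 1 was marked (odds ratio 0.0605, adjusted p of Fisher's exact test 1.12e-05), Foxa3 with 6.86 and 9.83, which has a neighbour, and Alb, Apoa1 and Apoa2 were not. The replicated peak at Foxa3 lay wholly upstream of the gene and may belong to the neighbour. Of 13 heart genes 1 was marked (odds ratio 0.0847, adjusted p of Fisher's exact test 0.000396), the pacemaker channel gene Hcn4 with 4.84 and 5.62, and Nppa, Nppb and Myh6 were not. Pluripotency and germ line genes were marked in 1 of 17 cases (odds ratio 0.0642, adjusted p of Fisher's exact test 2.13e-05), the germ cell gene Dazl with 3.13 and 4.82, and Pou5f1, Nanog and Zfp42 were not. Transcription factors of brain regions were marked in 4 of 18 cases (odds ratio 0.219, adjusted p of Fisher's exact test 0.00464). Bcl11b had 7.92 and 11.0 and En1 4.38 and 3.49, while Tbr1 had no peak and Emx1 and Eomes had one in replicate 1 only. Without replicate 2 the liver and gut odds ratio was 0.0956 with 2 genes marked, the heart odds ratio 0.21 with 3 and the germ line odds ratio 0.102 with 2, and without replicate 1 the last was 0.104. Without replicate 2 the brain call ended, with 9 of 18 genes marked and an adjusted p of Fisher's exact test of 0.417. The 4 calls held within CpG classes, with odds ratios of 0.059 for liver and gut, 0.0465 for heart, 0.0181 for germ line and 0.0227 for brain genes. With a window of 2500 bp the liver and gut and the brain odds ratios were 0.101 and 0.348, at a −log10 q of at least 5 the germ line and the brain odds ratios were 0.0297 and 0.0892, and without genes with a neighbour that of liver and gut was 0.0241.

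Genes of the ribosome, the proteasome and respiratory complex I were marked nearly throughout. All 78 cytosolic ribosomal protein genes were marked (odds ratio 112, adjusted p of Fisher's exact test 9.81e-18), at a median fold enrichment of 10.4, above all 10000 random lists. Rps20 had 18.4 and 14.7 and Rpl19 18.4 and 14.1. Proteasome subunits were marked in 36 of 39 cases (odds ratio 7.39, adjusted p of Fisher's exact test 1.35e-05) at a median of 8.86, percentile 99.8, with 14.5 and 10.7 at Psmd1 and 9.97 and 12.7 at Psma5. The 3 exceptions were Psma8, the subunit of the testis, without a peak, and Psmb11 of the thymus and Psmb8 of the immunoproteasome, each with a peak in replicate 1 only, so that 38 were marked without replicate 2 (odds ratio 16.3). All 36 subunits of respiratory complex I were marked (odds ratio 51.8, adjusted p of Fisher's exact test 4.63e-08), with 13.4 and 14.7 at Ndufb9, which has a neighbour, and 11.97 and 11.6 at Ndufa10. With 1 TSS per gene 76 ribosomal protein genes were marked and the odds ratio was 23.6. Within CpG classes the ribosomal call held (odds ratio 24.9, adjusted exact p of 0.000163), and the proteasome and complex I calls ended, with odds ratios of 2.39 and 13.9 and adjusted exact p of 0.17 and 0.0849. All 36 complex I genes were marked, so no higher share was possible for that list. Its ended call does not trace the marking to CpG content.

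Chemosensory receptor genes, which are expressed in few neurons each, seldom had a promoter peak in this whole tissue. A mark confined to few cells may give no peak, so this does not show that the mark is absent. Of 1092 olfactory receptor genes, among them Olfr1, Olfr10 and Olfr1000, 0 were marked in both replicates, with 5 in replicate 1 and 2 in replicate 2 (odds ratio 0.000284). The p of Fisher's exact test was too small to be represented. The odds ratio was 0.00129 without replicate 1, 0.00278 without replicate 2, 0.00277 within CpG classes and 0.00043 at a −log10 q of at least 5. Of 326 vomeronasal receptor genes 1 was marked (odds ratio 0.00314, adjusted p of Fisher's exact test 3.88e-123), Vmn1r4 with 7.84 and 10.2, which has a neighbour, and Vmn1r1, Vmn1r10 and Vmn1r100 had no peak. The replicated peak at Vmn1r4 lay wholly upstream of the gene and may belong to the neighbour. The vomeronasal odds ratio was 0.00479 without replicate 1, with 2 genes marked, 0.0137 within CpG classes and 0.00126 without genes with a neighbour, with 0 marked.

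Hox genes, which pattern the trunk and the hindbrain, were marked in 3 of 39 cases (odds ratio 0.0676, adjusted p of Fisher's exact test 2.06e-10). Hoxa1 had 3.59 in replicate 1 and 3.10 in replicate 2, Hoxd8 had 3.92 and 3.43 and Hoxd9 had 2.77 and 3.24. Their median of 3.34 stood at percentile 0.56. A peak in replicate 1 only lay at Hoxa5, Hoxa9 and Hoxa10, and in replicate 2 only at Hoxa4, Hoxc13, Hoxd1 and Hoxd3. No promoter peak was found in either replicate at Hoxa2, Hoxa3, Hoxa6, Hoxa7, Hoxa11 and Hoxa13, at Hoxb1 to Hoxb9 and Hoxb13, at Hoxc4, Hoxc5, Hoxc6, Hoxc8, Hoxc9, Hoxc10, Hoxc11 and Hoxc12, or at Hoxd4, Hoxd10, Hoxd11, Hoxd12 and Hoxd13. Without replicate 1 the odds ratio was 0.149 with 7 marked and without replicate 2 it was 0.122 with 6. It was 0.11 in the replicated list and 0.107 with every annotated transcript, with 5 marked in each, 0.0117 within CpG classes and 0.0131 at a −log10 q of at least 5, where 0 were marked.

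**Figure D4:**
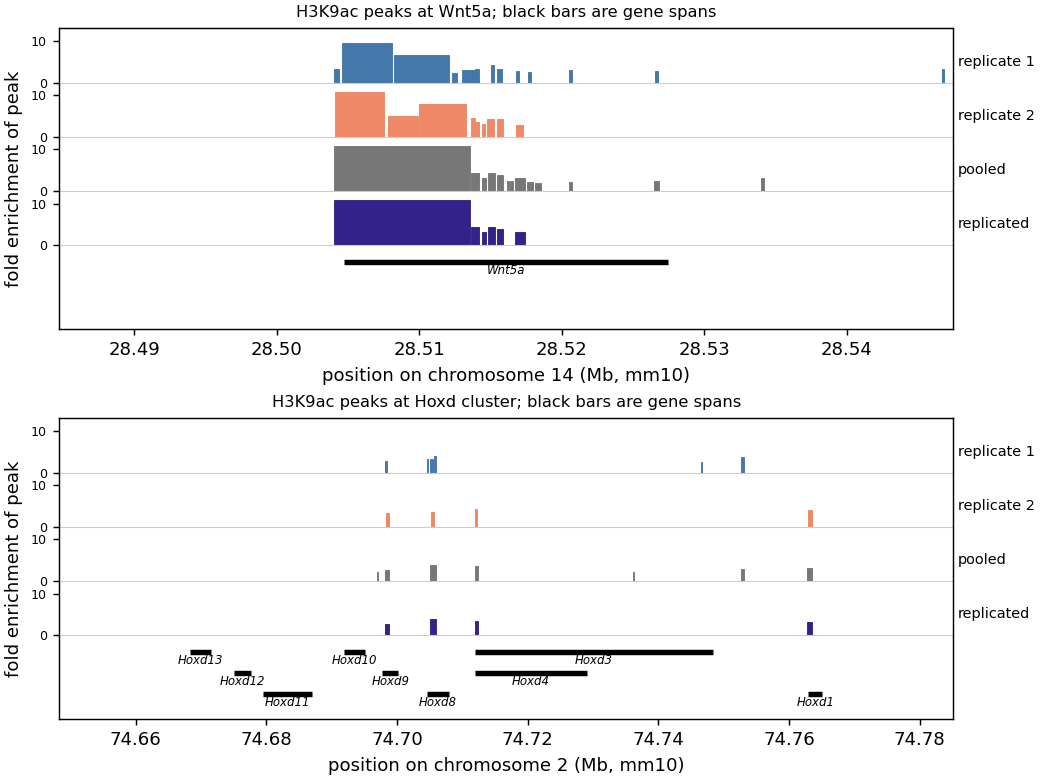
Maps in mm10 of the Wnt5a region (chromosome 14) and of the Hoxd cluster (chromosome 2), with position in Mb on the x axis; boxes are the peaks of replicate 1, replicate 2, the pooled reads and the replicated list, box height is fold enrichment on the same scale in both maps, and black bars are gene spans. Replicated peaks reach 10.9 at Wnt5a and 3.91 in the Hoxd cluster.

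The WNT and FGF ligand lists and the retinoic acid list missed the threshold of Fisher's exact test. WNT ligands were marked in 11 of 19 cases (odds ratio 0.957, adjusted p of Fisher's exact test 1). Wnt5a had 9.45 and 10.7 and Wnt11 7.84 and 6.99, Wnt1 had no peak, and Wnt2 and Wnt3 had one in replicate 1 or replicate 2 only. FGF ligands were marked in 11 of 22 cases (odds ratio 0.707, adjusted p of Fisher's exact test 0.569), with 10.6 and 11.98 at Fgf20, which has a neighbour, and 7.78 and 8.98 at Fgf2, and none at Fgf1, Fgf14 and Fgf17. With 13 WNT ligands marked in each replicate alone, the WNT odds ratio was 1.34 without replicate 1 and 1.31 without replicate 2, and the FGF odds ratio was 1.10 without replicate 1 and 1.18 in the authors' replicated list. Within CpG classes the odds ratios were 0.387 for WNT ligands (adjusted exact p of 0.0773) and 0.381 for FGF ligands (adjusted exact p of 0.0849), and at a −log10 q of at least 5 they were 0.501 and 0.41. Retinoic acid pathway genes were marked in 13 of 18 cases (odds ratio 1.74, adjusted p of Fisher's exact test 0.4). The receptor gene Rxrb, which has a neighbour, had 12.7 and 11.7 and the receptor gene Rarg 10.4 and 11.2. The replicated peak at Rxrb lay wholly upstream of the gene and may belong to the neighbour. Aldh1a1, which makes retinoic acid, Cyp26a1 and Cyp26c1, which degrade it, the binding protein gene Rbp1 and Stra6, a retinol transporter, were unmarked. The direction of this list turned at a −log10 q of at least 5, with an odds ratio of 0.843.

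The fifth comparison asked which genes have replicated peaks away from TSSs. Facial mesenchyme transcription factors had 1.88 distal peaks per gene within 50 kb, against a mean of 0.464 for random lists, above all 10000. The other lists above the central 95% of random lists were BMP and TGF-beta genes with 1.68, WNT ligands with 1.63, FGF feedback genes with 1.29, retinoic acid genes with 1.17, hedgehog genes with 1.14, osteoblast genes with 1.12 and cleft genes with 0.846. Below it lay Hox genes with 0.0513, pluripotency and germ line genes with 0.0588, olfactory receptors with 0.0485, vomeronasal receptors with 0.0245 and hair keratins with 0.0299. The random lists were not matched on promoter marking. Marked genes had a mean of 0.610 distal peaks and unmarked genes 0.252, so the percentiles do not separate distal peaks from marking. The lists above also exceeded the mean of marked genes, and those below were under that of unmarked genes. Members of a list that lie close together count the same peaks more than once. The osteoblast list fell to percentile 91.3 without replicate 2. Within 100 kb, 4 lists were above and 5 below, and the FGF feedback, retinoic acid, osteoblast and cleft lists were inside.

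The genes with most distal peaks were Gm20388, annotated over chr8:119910841-124345722, with 23, the transcriptional corepressor gene Bcor and Trim27 with 13 each, and Ahdc1 and the dynein gene Dnah2 with 10 each. These counts were not adjusted for the length searched, which was very long at Gm20388. The tallest distal peak, with a fold enrichment of 15.6, lay at chr15:85669681-85673293 in an intron of the non-coding gene Lncppara, 62271 bp from the TSS of Ppara. Its peaks in replicates 1 and 2 reached 15.4 and 12.7. Next came 4 intergenic peaks: chr1:165642348-165643260 with 14.8, nearest to Mpzl1, chr8:69716128-69716929 with 14.8, nearest to Zfp869, chr12:8640755-8641669 with 14.1, nearest to Pum2, and chr4:3874683-3875299 with 11.6, 2578 bp from the TSS of Mos.

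Some promoters had a peak in 1 replicate only. The highest in replicate 1 were Tnnc1, which has a neighbour, with 7.77, and E130218I03Rik and Gm30191 with 6.18 each from 1 shared peak. Both of the latter also have a neighbour. Impact with 5.67 and Actn2, the muscle α-actinin gene, with 5.07 followed. The Tnnc1 peak lay upstream of the gene and is also the promoter peak of its neighbour Nisch, named here after its values were seen, which was marked in both replicates with 7.77 and 9.23. The highest in replicate 2 were Fam19a1 with 7.74, Spaca6 with 6.49, Fam19a3 with 5.74, the somatostatin receptor gene Sstr4 with 5.25 and Skap2 with 5.24. Of the genes highest in either replicate, all but E130218I03Rik and Gm30191 had a promoter peak in the authors' replicated list. Its fold enrichment went from 3.42 at Fam19a3 to 9.21 at Tnnc1.

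The sixth comparison set the X chromosome against the autosomes. On X, 360 of 948 genes (37.97%) were marked, and on chromosomes 1 to 19, 12368 of 20780 (59.5%), with an odds ratio of 0.417 and a p of Fisher's exact test of 8.36e-39. The shares were 40.6% against 62.2% in replicate 1 and 40.2% against 61.7% in replicate 2. Marked promoters were also lower on X, with a median fold enrichment of 4.38 against 6.98 in replicate 1 and 4.74 against 7.49 in replicate 2. The odds ratio was 0.48 within CpG classes (exact p of 2.48e-15) and 0.341 without the gene families defined by symbol. At a −log10 q of at least 5 it was 0.26, with 20.8% of X genes and 50.3% of autosomal genes marked.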

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

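With 1 group of 2 replicates, no sample could be compared with the spread of a larger group and no contrast could differ between groups. What stood out was signal in peaks that the comparisons left out, and all tests of the pattern below were chosen after the result was seen. On the mitochondrial genome replicate 1 had 14 peaks, the pooled reads 11 and the replicated list 6, while replicate 2 had 0. The fold enrichment of these peaks was 1.31 to 2.27 in replicate 1 and 1.30 to 1.72 in the replicated list, and the highest −log10 q among them was 18.7 and 15.9. Unplaced scaffolds held 9 peaks in replicate 1, 16 in replicate 2, 15 in the pooled reads and 4 in the replicated list. Chromosome Y held 4 peaks of the pooled reads.

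The 6 mitochondrial peaks of the replicated list belong to a wider pattern, in which the replicated list holds peaks that 1 replicate lacks. Of its 21624 peaks, 938 overlapped replicate 1 only, 1053 replicate 2 only and 84 neither, and all 21624 had the coordinates of a pooled peak. A looser overlap rule does not account for them, since 2007 did not overlap a peak of both replicates by even 1 bp. Peaks near the calling limit are a candidate source. Of the 2075 peaks that lacked a replicate, 570 (27.5%) had a −log10 q of at least 5, against 87.7% of the other 19549. This −log10 q is that of the pooled reads, so it cannot tell how near a peak was to the limit in a single replicate. The source of the 2075 peaks stays open, and no biological explanation was tested, since the design gives none.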

How the results depend on the processing

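The TSSs of every annotated transcript and the CpG strata for X were chosen only after the result was seen. No paired analysis was possible because there is 1 group. Leaving out a replicate leaves 1 sample, so it gives values for that sample alone. Depth is unknown, so how far the weak peaks depend on it was not tested. Over the alternatives of the 33 gene lists, 287 values kept direction and side of the threshold, 19 reversed, 20 were weaker and 4 stronger, and for X the 10 alternatives run kept both. The cause of each change below was not tested, except that a −log10 q of 5 leaves fewer peaks and a replicate alone does not require the other.

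The shared part of the peaks was 38.9% with reciprocal overlap, 86.5% at a −log10 q of at least 5 and 80.3% among equal numbers of top peaks. The rank correlation was 0.808 with 1 bp of overlap, 0.673 at a −log10 q of at least 5 and 0.849 with −log10 p. The promoter share was 81.7% with 2500 bp, 45.4% in the pooled list, 83.6% at a −log10 q of at least 5 and 45.3% to 53.3% in single replicates. Genes marked were 57.6% with 500 bp, 59.9% with 2500 bp, 59.2% in the replicated list, 49.0% at a −log10 q of at least 5, 60.7% to 61.3% in single replicates, 56.6% with 1 TSS and 59.7% with every transcript.

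Within CpG classes 11 lists were called. Other lists changed direction or side of the threshold there, and of the changed lists only neurons were called. The FGF feedback, WNT feedback and complex I lists, all marked, and the enamel list, with none marked, could not move further in their direction. The odds ratios of the changed lists were 3.74 for osteoblasts, 0.416 for skeletal muscle, 4.45 for surface epithelium, 0.474 for terminal epidermis and 0.177 for enamel. They were 0.189 for neurons, 0.377 for olfactory epithelium, 1.33 for melanocytes, 1.32 for erythroid cells, 0.256 for leukocytes and 7.10 for FGF feedback. For hedgehog the value was 0.474, for BMP and TGF-beta 5.92, for WNT feedback 11.8 and for cleft genes 1.33. For the proteasome it was 2.39 and for complex I 13.9. At a −log10 q of at least 5 the odds ratios of changed lists were 0.208 for chondrocytes, 0.504 for surface epithelium and 0.0892 for neurons. The others were 0.226 for olfactory epithelium, 0.27 for endothelium, 2.15 for WNT feedback, 0.843 for retinoic acid and 1.83 for cleft genes. Surface epithelium had 1.26 with 500 bp, 2.44 with 1 TSS and 2.78 with every transcript. With 1 TSS, olfactory epithelium had 0.884, erythroid cells 0.328 and WNT ligands 1.04. Without neighbours, erythroid cells had 0.362 and WNT ligands 1.14. WNT ligands had 1.12 with 2500 bp and 1.15 in the replicated list, and FGF ligands 1.18 in the latter. With 1 replicate left out, the ranges were 0.977 to 1.37 for olfactory epithelium, 0.277 to 0.366 for erythroid cells, 0.263 to 0.632 for brain factors, 2.13 to 5.69 for hedgehog, 1.31 to 1.34 for WNT ligands and 0.898 to 1.10 for FGF ligands. Of the values for single lists, 7 of height and 17 of distal peaks moved across the limits of the random lists, and 89 and 148 did not; with the pooled list the osteoblast and germ line distal values lay inside, at percentiles 94.75 and 4.47.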

Other observations

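The tests of the families, of CpG content, gene families and dose on X, and of escape genes against genes of like CpG ratio were chosen only after the result was seen; those of escape genes among X genes and of the widths had their outcomes written down first. Of families picked by symbol, 18 were tested. Semaphorins, guidance cues of neurons and vessels, were marked in 19 of 20 cases (odds ratio 9.21, adjusted p of Fisher's exact test 0.00103), ADAMTS proteases of the extracellular matrix in 17 of 19 (4.96, adjusted p of Fisher's exact test 0.00871) and collagens in 33 of 44 (2.06, adjusted p of Fisher's exact test 0.0401), and the 3 calls held within CpG classes with adjusted exact p of 0.00023, 0.0302 and 0.000376. The 3 families were low, with median fold enrichments of 5.25 for semaphorins, 4.97 for ADAMTS proteases and 4.53 for collagens, all below the central 95% of random lists. These random lists were not matched on CpG ratio. Zinc finger genes named Zfp were marked in 322 of 391 cases (3.34, adjusted p of Fisher's exact test 8.58e-23), voltage-gated potassium channel genes in 15 of 17 (4.39, adjusted p of Fisher's exact test 0.0176) but at a median of only 3.75, and all 78 mitochondrial ribosomal protein genes (adjusted p of Fisher's exact test 1.07e-17), and these calls too held within the classes. All 10 frizzled receptors and 19 of 22 ephrins and Eph receptors were marked (adjusted p of Fisher's exact test 0.0115 and 0.0123). Both calls ended within the classes, with adjusted exact p of 1 for each. The frizzled odds ratio went from 14.9 to 2.41 and that of ephrins and Eph receptors turned from 3.94 to 0.901. With all 10 frizzled genes marked, no higher share was possible for them.

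Clustered protocadherins were marked in 3 of 56 cases (odds ratio 0.046, adjusted p of Fisher's exact test 1.65e-16, and 0.0108 with an adjusted exact p of 5.71e-28 within CpG classes). The 2 tallest were Pcdhgc3 and Pcdhac2. Claudins were marked in 6 of 23 (0.262, adjusted p of Fisher's exact test 0.00455), cytochrome P450 genes in 18 of 99 (0.159, 1.04e-15 by Fisher's exact test), serpins in 8 of 61 (0.112, 6.75e-13 by Fisher's exact test) and beta-defensins in 0 of 42 (0.00828, 3.57e-16 by Fisher's exact test), and within the classes the call ended for claudins, with an odds ratio of 0.331 (adjusted exact p of 0.0688), and for P450 genes and serpins, with 0.922 and 1.05. Replication-dependent histone genes were marked in 53 of 67 (2.62, adjusted p of Fisher's exact test 0.00103). Within the classes the direction turned and they were called lower, with an odds ratio of 0.186 (adjusted exact p of 6.64e-05). Forkhead factors with 23 of 44, Sox factors with 13 of 19, T-box factors with 7 of 15 and solute carriers with 202 of 352 were not called, with adjusted p of Fisher's exact test of 0.5, 0.516, 0.5 and 0.663. Within the classes forkhead factors and solute carriers were lower, with adjusted exact p of 8.48e-07 and 0.0447, and the Sox direction turned, with an odds ratio of 0.354 against 1.47 (adjusted exact p of 0.0561). Members of several of these families are neighbours and can share peaks. At 4372 marked genes with 1 annotated TSS and no neighbour, the summit of the tallest peak lay downstream of the TSS in 90.1% of cases in replicate 1 and 89.9% in replicate 2, at a median of 246 and 239 bp.

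X-linked promoters were marked less often and lower than autosomal ones. Fewer CpG-rich promoters on X do not alone account for the lower share, since the odds ratio within CpG classes was 0.48 (exact p of 2.48e-15). Families without marks do not alone account for it either. The odds ratio was 0.465 (p of Fisher's exact test 1.33e-10) without genes named Gm or Rik and genes whose symbol stem 5 or more genes share. Both together were not tested, and neither test covers height. In the upper 5 CpG classes the median height on X was 0.632 times that of autosomes (0.654 in replicate 1, bootstrap interval 0.621 to 0.687, and 0.629 in replicate 2, 0.594 to 0.657). This ratio restates the pattern and is no test of a lower dose of the X, from 1 copy in males or an inactive copy in females, which cannot be told apart in these pools of both sexes and stays open. Of 8 genes known to escape inactivation, written down before their values were seen, 7 were marked, and their median of 7.01 stood at percentile 100 of random lists of marked X genes and at percentile 33.6 of autosomal genes from the same CpG classes: Ddx3x, Kdm5c and Kdm6a were the 3 tallest of 360 promoters and Eif2s3x the 11th, while Pbdc1, Utp14a and Mid1 ranked 182, 282 and 291 and Car5b was unmarked. A candidate explanation is that an inactive X lowers the other promoters, but the 4 tall genes also have partners on Y and are used by most cells, and that was not tested.

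Promoter peaks of facial mesenchyme transcription factors were wide for their height, with a median width, as the mean of the replicates, of 1016 bp, against 788.5 bp for random lists matched on 10 classes of fold enrichment (percentile 99.9). Neither the number of annotated TSSs nor the CpG ratio within 500 bp of the 5′-most TSS accounts for it alone. The percentile was 99.88 when matched on the number of TSSs as well, with the highest numbers joined, and 99.875 when matched on CpG ratio. Both were not matched together. The length of CpG-rich sequence was not measured, so CpG content in that wider sense stays open. In the replicates alone it was 99.83 and 99.61, which says nothing on the joining of peaks in the pooled reads, since the widths come from the replicate lists. Of the 24 lists, 6 were wide for their height in the same sense, and the others were osteoblast, hedgehog, BMP and TGF-beta, retinoic acid and cleft genes, with median widths of 1393, 2088.5, 1483.5, 1407.5 and 1136.5 bp, whereas proteasome genes were narrow with 931 bp (percentile 1.95) and ribosomal protein genes with 1278.5 bp stood at percentile 90.7 (81.9 in replicate 1 and 97.8 in replicate 2). The osteoblast list includes the matrix genes Sparc and Col1a1, some genes stand on several lists, and no biological explanation was tested.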
